A study of Mus musculus with 6 samples.

How the data were processed

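RNA from 3 populations of mouse hair follicle cells was measured on Affymetrix arrays of the mouse genome, a design with several 25-base probes for each transcript that are summarised into a probe set. Per the labels, the cells were sorted by flow cytometry from the back skin of female CD-1 mice, total RNA was extracted with Trizol, and biotin-labelled cRNA was made from 2 µg of RNA per array. The deposited values are intensities of probe sets on a linear scale, from 3.83 to 31188.2 over the 6 arrays, and RMA is named without a version or a role in the submitters' processing notes. RMA usually subtracts background from the perfect-match probes, quantile-normalises the arrays and fits a median polish on the log2 scale. The software, the chip definition and the return to a linear scale are not given in the sources used here. Such summaries compress large fold changes and dim signals, and quantile normalisation assumes that the overall distribution of RNA is alike in the populations. No detection calls were used, so a low intensity was not read as absence of a transcript. The background level of 19.5 used to mark dim groups was chosen after the data were seen. The median intensity per array lay between 22.8 and 24, and the quartiles were nearly equal between arrays. For arrays, the number of replicates limits the precision: each group held 2.

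Intensities were put on the log2 scale before all tests. Of 45101 probe sets, 64 control probe sets were left out, 34945 others carried 1 gene symbol in the platform annotation, 932 carried several and 9160 carried none. The Entrez identifiers of 34741 of the probe sets with 1 symbol were found in a RefSeq gene table, and 0 symbols had to be updated. Genes were tested through 1 probe set each, the one with the highest mean over all 6 arrays among those paired with that gene alone, which left 18193 genes. Of these, 9010 had 2 or more probe sets of their own. No filter on dim genes was applied.

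All 6 arrays were fitted in 1 model of group means with limma 3.58.1 (lmFit, contrasts.fit and eBayes, R 4.3.3). The residual degrees of freedom were 3 per gene and the prior added 4.25. The tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over genes within each comparison, and the threshold was an adjusted p of 0.05. Differences are given as folds or on the log2 scale with their standard error (SE) from this fit; means and standard deviations (SD) are over the 2 arrays of a group. On simulated data around the real gene means, 100 of 18193 genes were changed 2-fold and 100 changed 4-fold. The noise was independent between genes, with spreads drawn at random from the prior of the real fit. There the fit recovered 25% of 2-fold and 88% of 4-fold changes between aHF-SC and qHF-SC, and 5.83% of its calls were false. For HF-TAC against aHF-SC the recovery was 21% and 89%, with 3.51% false calls. For HF-TAC against qHF-SC it was 20% and 90%, with 5.17% false calls. These rates need not hold for the real arrays, where 6.28%, 17.5% and 26.3% of genes were called and noise may be shared between genes.

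The groups, the tests, the gene lists, the rule for named genes and most of the alternatives were fixed before the data were examined. The 19 gene lists covered bulge stem cell genes, matrix and hair lineage regulators, inner root sheath genes, hair shaft genes, basal adhesion genes, G1/S and DNA replication genes, G2/M and mitosis genes, CDK inhibitors and pocket proteins, the BMP and TGF-beta, Wnt, Hedgehog and Notch pathways, Polycomb genes, histone lysine demethylases and trithorax genes, DNA methylation genes, ribosome biogenesis genes, glycolysis genes, non-skin lineage transcription factors and dissociation stress genes. A further 11 lists held markers of other cells that a skin digest or a sorting gate could hold: differentiated keratinocytes, infundibulum with isthmus and sebaceous gland, companion layer, dermal fibroblast, dermal papilla, melanocyte, endothelial, immune, Merkel and Schwann, muscle and erythroid cells. The lists came from general knowledge of the tissue and share some members. List genes without a probe set of their own were not analysed here. The 30 lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 30 lists within each comparison. They were tested again with an estimated correlation and with fry, a rotation test of each list by itself. With an estimated correlation, camera takes its p-value from the 3 residual degrees of freedom. Few lists can then pass after adjustment over 30 lists. A loss there may reflect the few arrays rather than members that vary together.

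The genes named are the 8 largest rises and 8 largest falls per comparison among genes past the threshold whose arrays did not overlap between the groups, up to 4 members per list with the largest change past the threshold (and the 2 members with the smallest p where fewer than 2 passed), and a fixed set of sorting markers and lineage genes. Some of these genes are not printed below, and the counts of named genes include them. Alternatives covered the choice of probe set, the filter on dim genes, scaling, the eBayes prior, the arrays entering the fit, array weights, a test against a 2-fold change, the replicate number as a block, and leaving out each array in turn; the group left with 1 array is then assumed to vary like the others. One choice left out the _x_at and _s_at probe sets, called cross-hybridising below after their suffix alone. No cross-hybridisation was measured, and all probe sets used were paired with 1 gene. Summaries and plots were made with Python and matplotlib from the same values.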

Results

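Transcript levels were measured in 3 populations along the hair follicle lineage of mouse back skin, with 2 arrays for each. The quiescent hair follicle stem cells (qHF-SC), from resting follicles, were sorted with integrin α6 and CD34 from mice of postnatal days 52 to 60. The activated hair follicle stem cells (aHF-SC) were sorted with GFP, integrin α6 and CD34 from mice of postnatal days 28 to 30. The transient-amplifying matrix cells (HF-TAC), the short-lived dividing cells at the follicle base that give rise to the hair and its sheaths, were sorted with GFP, integrin α6 and ephrin-B1 at postnatal days 28 to 30. The labels do not say what carried the GFP or on which side of each marker the gates were set. The expression arrays belong to a study of chromatin states in this lineage. Age and sorting scheme change together with cell state between qHF-SC and the other groups, and sorting scheme changes with cell type between aHF-SC and HF-TAC. No label says that the replicates came from separate animals, so the p-values measure the spread between these arrays, which may be technical.

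Replicate arrays correlated across genes at r = 0.9915 in qHF-SC, 0.9911 in aHF-SC and 0.9885 in HF-TAC on the log2 scale, where genes are not independent replicates. Genes more than 2-fold apart between the replicates numbered 202, 215 and 454. The first principal component held 68.1% of the variance and set HF-TAC apart from both stem cell groups. The second held 19.4% and set aHF-SC, at -37.1 and -38.5, apart from qHF-SC, at 17.0 and 35.8, and HF-TAC, at 17.0 and 5.83. A group mean of at most 19.5, the highest median that the lists of non-skin transcription factors and erythroid genes reached on any array, was read as background. The lower group was at background for 12 of the 66 named genes past the threshold in aHF-SC against qHF-SC, 11 of 101 in HF-TAC against aHF-SC and 24 of 112 in HF-TAC against qHF-SC. The size and rank of such a fold are uncertain.

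The transcripts of the surface markers used in sorting describe the gates and are no finding between the groups. Cd34 had an intensity of 7871 ± 970 (SD, n = 2) in qHF-SC, 2817 ± 612 (SD, n = 2) in aHF-SC and 20.5 ± 7.39 (SD, n = 2) in HF-TAC. Itga6, which encodes integrin α6, stood at 2466 ± 489, 2525 ± 350 and 962 ± 153 in the same order. Efnb1, which encodes ephrin-B1, stood at 501 ± 114, 761 ± 48.2 and 927 ± 116. Its difference passed the test between HF-TAC and qHF-SC (1.87-fold, limma adjusted p = 0.0145) and in neither of the other comparisons (adjusted p = 0.131 and 0.448). The Efnb1 call ended without qHF-SC replicate 2 (adjusted p = 0.0907) and without HF-TAC replicate 2 (0.0735).

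**Figure D1:**
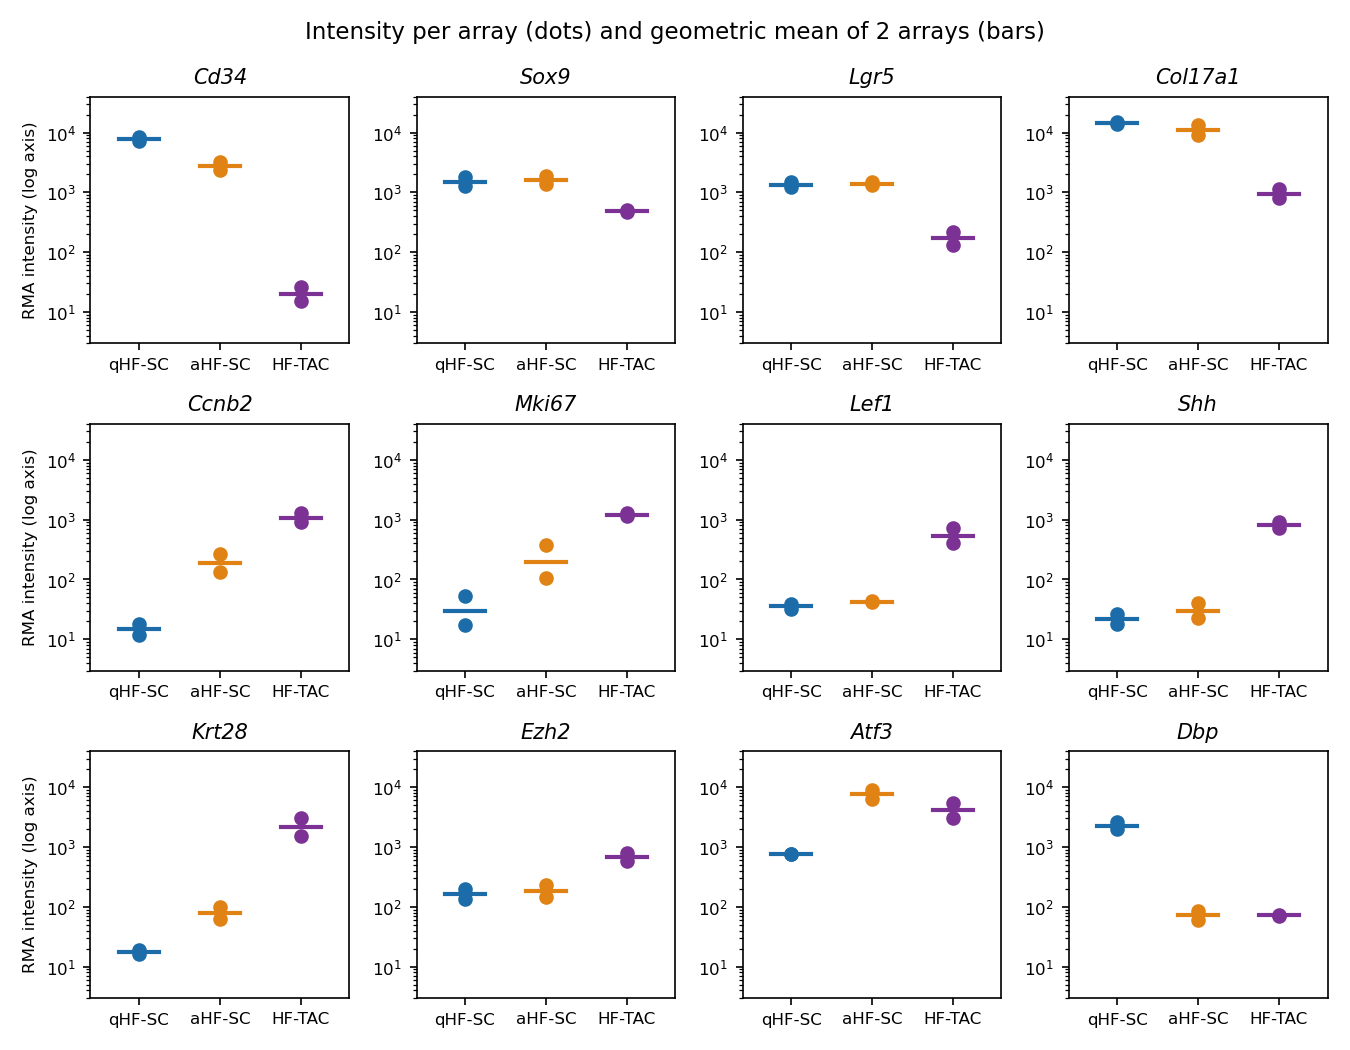
Probe set intensity (RMA, linear values on a log axis) of 12 genes in qHF-SC, aHF-SC and HF-TAC; dots are single arrays and bars the geometric mean of the 2 arrays. Sox9 and Lgr5 lie at similar levels in both stem cell groups and lower in HF-TAC, Ccnb2 climbs over the 3 groups, and Dbp is 31.5-fold lower in aHF-SC than in qHF-SC.

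The first comparison asks how activated stem cells differ from quiescent ones. Cell division genes were higher in aHF-SC: of 31 measured G2/M and mitosis genes, 20 rose and the other 11 did not pass, and 30 rose when adjusted over the list alone. Their median difference was 4.52-fold (camera adjusted p = 4.08e-25; adjusted p = 0.749 with an estimated correlation). Ccnb2, the mitotic cyclin B2, rose 12.8-fold (3.67 ± 0.35 SE on the log2 scale, adjusted p = 0.00348), from an intensity of 15.0 ± 4.30, at background, to 198 ± 90.7 (SD, n = 2). Cdc20, an activator of the anaphase-promoting complex, rose 8.53-fold (log2 difference 2.27 with the mean of its 3 probe sets) and Birc5, which encodes survivin of the chromosomal passenger complex, 9.45-fold. The Birc5 call ended without qHF-SC replicate 2 (adjusted p = 0.0573). Mki67, a proliferation marker, differed by 2.73 ± 0.65 and missed the threshold with an adjusted p of 0.0562. It passed in 5 of the other settings and without aHF-SC replicate 2 (adjusted p = 0.0366).

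Of 30 G1/S and DNA replication genes 6 rose, or 12 adjusted over the list alone, with a median of 1.49-fold (camera adjusted p = 1.87e-08; adjusted p = 0.848 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, rose 4.45-fold, Uhrf1, a factor of maintenance DNA methylation, 4.25-fold, and Mcm5 of the replicative helicase 3.75-fold. The Mcm5 log2 difference was 1.14 with the mean of its 3 probe sets. The Rrm2, Uhrf1 and Mcm5 calls ended without qHF-SC replicate 2 (adjusted p = 0.106, 0.0695 and 0.0632), and that of Rrm2 also without aHF-SC replicate 1 (0.12) or 2 (0.0577). Among CDK inhibitors Cdkn1c (p57) fell, being 2.68-fold lower, and Cdkn2c (p18) rose 1.83-fold, while the list of 11 as a whole did not pass (adjusted p = 0.332). The Cdkn1c call ended without qHF-SC replicate 2 (adjusted p = 0.0739) and without aHF-SC replicate 1 (0.0637). The Cdkn2c call ended with the replicate number as a block (adjusted p = 0.0766), without qHF-SC replicate 1 (0.189) or 2 (0.18) and without aHF-SC replicate 1 (0.185) or 2 (0.0591). The DNA methylation list had 2 of 13 members higher, Dnmt3l (4.32-fold, from background) and Uhrf1, or 6 adjusted over the list alone, and missed the threshold (camera adjusted p = 0.0612). It passed with the mean of each gene's probe sets (adjusted p = 0.0325), with scaling to the 75th percentile (0.0343), without qHF-SC replicate 1 (0.0178) and without aHF-SC replicate 2 (0.0497). Of 22 Polycomb genes 0 passed by limma, with 6 at an unadjusted p under 0.05; Ezh2 differed by 0.19 ± 0.29 SE (adjusted p = 0.802).

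Genes of the dissociation stress list, which respond within minutes to mechanical or enzymatic stress, were higher in aHF-SC, as were the division genes. Of 20 members 12 rose, or 16 adjusted over the list alone, with a median log2 difference of 1.67 (camera adjusted p = 3.27e-13; adjusted p = 0.749 with an estimated correlation). The transcription factor genes Atf3 and Nr4a1 rose 9.85-fold and 7.75-fold, and Junb, of the AP-1 family, 6.57-fold. Replicate 2 of aHF-SC had the higher median intensity of the stress list (6080 against 3650 in replicate 1). It had the lower median of the mitosis list (72.9 against 144). The Junb call ended without qHF-SC replicate 2 (adjusted p = 0.101). Markers of differentiated keratinocytes moved the other way, with 3 of 14 lower, or 7 lower and 1 higher adjusted over the list alone (median log2 difference -0.483, camera adjusted p = 0.000464; adjusted p = 0.848 with an estimated correlation). Lor, a protein of the cornified envelope, was 14.0-fold lower, with an adjusted p of 0.0282 that missed the threshold whenever a qHF-SC or aHF-SC array was left out (adjusted p = 0.113 and 0.156 without qHF-SC replicates 1 and 2, 0.0666 and 0.129 without aHF-SC replicates 1 and 2), with the mean of its probe sets (0.0517) and without cross-hybridising ones (0.0876). Its log2 difference was -4.48 and -3.13 without aHF-SC replicates 1 and 2, -2.76 with that mean and -3.06 without the cross-hybridising probe sets, against -3.80. Krtdap was 3.20-fold and Krt10, a suprabasal keratin, 2.57-fold lower, and with the same arrays left out in turn both missed the threshold too (adjusted p = 0.0701, 0.143, 0.0955 and 0.0929 for Krtdap, and 0.08, 0.0852, 0.0617 and 0.0817 for Krt10). Of the muscle list, Acta2 and Tagln, both of the contractile smooth muscle type, rose 48.8-fold and 28.2-fold. The list of 9 did not pass (adjusted p = 0.0881), but did without qHF-SC replicate 2 (adjusted p = 0.0157). The Acta2 value rested on 1 of its 3 probe sets; with the mean of them it was 1.87 on the log2 scale, and with probe sets that can cross-hybridise left out it was -0.15 on the log2 scale and did not pass (adjusted p = 0.694).

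Bulge stem cell genes were not shifted as a list: 1 of 22 rose and 3 fell, or 4 and 4 adjusted over the list alone (camera adjusted p = 0.606). The list's median was 0.0177 on the log2 scale, whereas its mean of -0.115 and the test pointed down. Bmp6 rose 3.86-fold, and Dkk3 (3.03-fold) and Postn (2.91-fold) were lower. The Bmp6 and Postn calls ended without qHF-SC replicate 2 (adjusted p = 0.0607 and 0.081). The other fall was in Cd34, a gate marker (2.82-fold), whose call ended without qHF-SC replicate 1 (adjusted p = 0.076) or 2 (0.169) and without aHF-SC replicate 1 (0.128) or 2 (0.0589). The stem cell transcription factor genes Sox9 (0.08 ± 0.23 SE), Lhx2 (-0.51 ± 0.32), Nfatc1 (-0.94 ± 0.23) and Tcf7l1 (1.09 ± 0.27) and the receptor gene Lgr5 (0.06 ± 0.25) did not pass, with adjusted p from 0.0598 to 0.942. With the mean of its 5 probe sets the Nfatc1 log2 difference was -0.26 (limma adjusted p = 0.353). Nfatc1 did pass with scaling to the 75th percentile (adjusted p = 0.0299), with quantile normalization (0.0395), with array weights (0.0481) and without aHF-SC replicate 2 (0.0326), and Tcf7l1 with scaling to the 75th percentile (0.0292) and without aHF-SC replicate 1 (0.0366). In the BMP and TGF-beta list Grem1, a BMP antagonist, and Ltbp2, of the latent TGF-beta binding protein family, were 6.79-fold and 6.31-fold lower, in a list with 1 of 27 members higher and 4 lower (5 lower and 4 higher adjusted over the list alone) that did not pass (camera adjusted p = 0.28). Of the Wnt list Wnt5a rose 4.95-fold, through 1 of its 4 probe sets, and Dkk3, Fzd3 (2.85-fold) and Axin2 (2.69-fold) were lower. Fzd3 rested on 1 of 6 probe sets, and Wnt5a was at background in qHF-SC. With the mean of each gene's probe sets the log2 differences were 0.86 for Wnt5a (adjusted p = 0.16), -0.39 for Fzd3 (adjusted p = 0.179) and -0.71 for Axin2, which still passed. The Axin2 call ended without qHF-SC replicate 2 (adjusted p = 0.106) and without aHF-SC replicate 2 (0.0538). The Wnt5a call also ended without qHF-SC replicate 2 (adjusted p = 0.0695), without aHF-SC replicate 1 (0.0838) and without aHF-SC replicate 2 (0.0597). The Wnt list did not pass (adjusted p = 0.757), and neither did the basal adhesion list, with 2 of 16 higher and 2 lower, or 3 and 4 adjusted over the list alone (adjusted p = 0.817).

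Genes of the inner root sheath, the layer that moulds the hair, were higher in aHF-SC: 4 of 12 rose, or 5 adjusted over the list alone (median 2.03-fold, camera adjusted p = 0.00111; adjusted p = 0.749 with an estimated correlation). Krt25 rose 8.83-fold and Padi3, which citrullinates trichohyalin, 5.86-fold. The Krt25 call ended without qHF-SC replicate 2 (adjusted p = 0.115) and without aHF-SC replicate 2 (0.0547). The Krt25 log2 difference was 3.79 without aHF-SC replicate 1 and 2.49 without replicate 2. Matrix regulators passed with 2 of 26 higher, or 3 adjusted over the list alone (camera adjusted p = 0.0248; adjusted p = 0.909 with an estimated correlation). That call ended without qHF-SC replicate 2 (adjusted p = 0.191), without aHF-SC replicate 2 (0.118) and with the cross-hybridising probe sets left out (0.0704). Of the hair shaft list Krt35 rose 10.1-fold and Selenbp1 was 2.64-fold lower, and the list of 15 did not pass (adjusted p = 0.254). Krt25, Krt35 and Padi3 were at background in qHF-SC. The Krt35 call ended without qHF-SC replicate 1 (adjusted p = 0.0514) or 2 (0.0671). The Selenbp1 call ended without qHF-SC replicate 1 (0.109) or 2 (0.25), without aHF-SC replicate 1 (0.192) or 2 (0.0702), with the mean of its probe sets (0.0554) and with centring on the median (0.0518). The ribosome biogenesis list, with 1 of 25 higher and 1 lower, also adjusted over the list alone, had an adjusted p of 0.254 as well. Of the infundibulum, isthmus and sebaceous gland list 2 of 13 rose and 1 fell, also adjusted over the list alone, and the list did not pass (adjusted p = 0.606). Hair keratins are close paralogs whose probe sets can share signal, so the identity of single members is uncertain. Carry-over of HF-TAC into the aHF-SC sort, taken up below, was not excluded for these hair lineage genes.

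The largest other falls by fitted fold were in Cck, which encodes cholecystokinin (133-fold; -7.06 ± 0.20 SE, adjusted p = 4.64e-05), at 1534 ± 148 in qHF-SC and 11.5 ± 0.465, which is background, in aHF-SC (SD, n = 2), and in Dbp, a clock output factor (31.5-fold), Wfdc3 (17.3-fold), Ngef (17.1-fold) and Angptl7 (17.0-fold). The largest other rises were in the gap junction gene Gjb2 (61.5-fold; 5.94 ± 1.32 SE, adjusted p = 0.0447), Spon1 (29.0-fold), Pla2g7 (21.6-fold) and Cps1 (17.9-fold). Spon1 rested on 1 of its 4 probe sets, and its log2 difference was 1.66 with the mean of them, which still passed. That of Wfdc3, which rested on 1 of 2, was then -2.07. Spon1, Pla2g7 and Cps1 were at background in qHF-SC. Without aHF-SC replicate 1 the log2 differences of Spon1 and Cps1 were 3.80 and 3.02, and without aHF-SC replicate 2 they were 5.92 and 5.31. Without qHF-SC replicate 2 the Spon1 and Cps1 calls ended (adjusted p = 0.0618 and 0.112). The Gjb2 replicates in qHF-SC stood at 435 and 16.2; the call ended with qHF-SC replicate 2 left out, where the log2 difference was 3.57 (adjusted p = 0.0639; 8.32 without replicate 1, where the call held), with either aHF-SC array left out (adjusted p = 0.182 and 0.134), with the replicate number as a block (0.0597) and, by the adjustment alone since it has 1 probe set, with the mean of each gene's probe sets (0.0548).

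In all, 558 of 18193 genes were higher and 584 lower in aHF-SC than in qHF-SC by limma. The arrays of the groups did not overlap for 50.8% of genes, where chance gives 33.3%. The counts depended on single arrays. They were 54 and 70 without qHF-SC replicate 2, 379 and 258 without qHF-SC replicate 1, 131 and 172 without aHF-SC replicate 1, and 233 and 242 without aHF-SC replicate 2. Of the 66 named genes past the threshold here, 21, 46, 35 and 35 passed in the same order, and 19 passed whichever array was left out, among them Ccnb2, Cdc20, Atf3, Nr4a1, Dkk3, Grem1, Ltbp2, Padi3, Cck and Dbp. A test against a 2-fold change left 17 higher and 41 lower.

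The comparison of HF-TAC with aHF-SC, of equal age, sets the dividing progeny against the stem cells. Stem cell genes were lower in HF-TAC: 19 of 22 bulge stem cell genes fell and the other 3 did not pass, and 20 fell adjusted over the list alone. Their median log2 difference was -2.71 (camera adjusted p = 6.57e-20; adjusted p = 0.314 with an estimated correlation). Apart from Cd34, the Wnt antagonist gene Sfrp1 was 22.5-fold lower (-4.49 ± 0.22 SE, adjusted p = 0.000112), the matrix protein genes Npnt and Postn 16.0-fold and 13.7-fold, and Lgr5 8.29-fold, from 1403 ± 87.8 to 175 ± 63.2 (SD, n = 2). The transcription factor genes Lhx2 (4.09-fold), Tcf7l1 (3.61-fold), Sox9 (3.26-fold) and Nfatc1 (3.23-fold) were lower as well. Lgr5 rested on 1 of its 2 probe sets, and its log2 difference was -1.49 with the mean of them. That of Npnt was -3.13 and that of Nfatc1 -1.04 with the mean of their probe sets. Basal adhesion genes fell as well, with 13 of 16 lower, or 14 adjusted over the list alone (median log2 difference -1.4, camera adjusted p = 8.34e-12; adjusted p = 0.314 with an estimated correlation). The list holds Itga6, a gate marker (2.63-fold lower); Col17a1 of the hemidesmosome was 11.5-fold lower, Lamb3 6.54-fold and Itgb4 5.14-fold.

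Regulators of the matrix and hair lineages were higher in HF-TAC, with 12 of 26 rising and 1 falling, or 15 and 2 adjusted over the list alone (median log2 difference 1.27, camera adjusted p = 1.36e-07; adjusted p = 0.398 with an estimated correlation). Shh, the morphogen, rose 27.0-fold (4.75 ± 0.30 SE, adjusted p = 0.000258), from 31.4 ± 11.9 to 821 ± 121 (SD, n = 2), through 1 of its 2 probe sets. Cux1 rose 13.2-fold, the Wnt effector gene Lef1 12.7-fold, Wnt5a 9.07-fold and Msx2 8.47-fold, while Hoxc13 differed by 0.48 ± 0.34 and did not pass, except without HF-TAC replicate 1 (1.03, adjusted p = 0.034). With the mean of each gene's probe sets the log2 differences were 2.45 for Shh, 2.36 for Cux1, 2.28 for Wnt5a and 1.64 for Msx2, all past the threshold. Inner root sheath genes rose, with 9 of 12 higher, or 10 adjusted over the list alone (median log2 difference 2.18, camera adjusted p = 4.47e-08; adjusted p = 0.314 with an estimated correlation), led by Krt28 (27.5-fold) and Krt25 (23.7-fold; log2 difference 3.92 and 5.22 without aHF-SC replicates 1 and 2). Of the hair shaft genes 6 of 15 rose, also 6 adjusted over the list alone (camera adjusted p = 0.000589; adjusted p = 0.398 with an estimated correlation), with Krt35 39.0-fold (log2 difference 5.92 and 4.65 without HF-TAC replicates 1 and 2) and Selenbp1 13.1-fold higher. Another hair protein gene went the other way: Krtap17-1 was 32.7-fold lower in HF-TAC, where it was at background, with a log2 difference of -4.39 and -5.67 without aHF-SC replicates 1 and 2.

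All 31 measured G2/M and mitosis genes were higher in HF-TAC than in aHF-SC, over all genes and adjusted over the list alone (median log2 difference 2.52, camera adjusted p = 8.44e-22; adjusted p = 0.398 with an estimated correlation). Kif11, a spindle motor, rose 9.04-fold and the checkpoint kinase gene Bub1 8.87-fold, with log2 differences of 2.41 and 2.02 for the mean of their probe sets. Without aHF-SC replicate 1 these differences were 4.0 for Kif11, 3.96 for Bub1 and 3.52 for Mki67, and without aHF-SC replicate 2 they were 2.35, 2.34 and 1.68. Mki67 rose 6.08-fold, but missed the threshold without aHF-SC replicate 2 (adjusted p = 0.147), without HF-TAC replicate 1 (0.0872) and without HF-TAC replicate 2 (0.116). Of 30 G1/S genes 28 rose, also 28 adjusted over the list alone (median log2 difference 1.65, camera adjusted p = 2.68e-19; adjusted p = 0.398 with an estimated correlation), among them Gins1 (5.66-fold) and Mcm10 (5.10-fold), each through 1 of its probe sets, with log2 differences of 1.48 and 0.76 for the mean of them. Of 25 ribosome biogenesis genes 18 rose, or 23 adjusted over the list alone (median log2 difference 0.788, camera adjusted p = 3.08e-12; adjusted p = 0.398 with an estimated correlation); Odc1, of polyamine synthesis, which was 2.81-fold lower in aHF-SC than in qHF-SC, rose 5.74-fold and Dkc1, of the snoRNP complex, 2.86-fold. The Odc1 call between the stem cell groups ended without qHF-SC replicate 2 (adjusted p = 0.0677), without aHF-SC replicate 1 (0.0788) and without aHF-SC replicate 2 (0.0666).

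Ezh2, the methyltransferase of Polycomb complex PRC2, rose 3.68-fold (1.88 ± 0.29 SE, adjusted p = 0.00469) and Phc1 3.02-fold, while Phf1 was 2.57-fold lower; 3 of 22 Polycomb genes rose and 3 fell, or 7 and 4 adjusted over the list alone, and the list did not pass (adjusted p = 0.578). Of 20 histone demethylase and trithorax genes 0 passed by limma, with 2 at an unadjusted p under 0.05, and that list did not pass either (adjusted p = 0.712). The Phc1 call ended without aHF-SC replicate 1 (adjusted p = 0.0563) and the Phf1 call without aHF-SC replicate 2 (0.0508). Of 13 DNA methylation genes 5 rose and 1 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.0178; adjusted p = 0.405 with an estimated correlation). The members went apart: Hells, a chromatin remodeller, rose 5.03-fold, Uhrf1 4.06-fold and the maintenance methyltransferase gene Dnmt1 2.26-fold, and the de novo methyltransferase gene Dnmt3a was 3.53-fold lower. Hells rested on 1 of its 3 probe sets, and its log2 difference was 1.04 with the mean of them. Uhrf1 is also a member of the G1/S list, whose median log2 difference here was 1.65. The rises of Ezh2, Hells, Uhrf1 and Dnmt1 were not tested apart from those of division genes. The Dnmt1 call ended without aHF-SC replicate 2 (adjusted p = 0.0631). The list's call ended without the cross-hybridising probe sets (adjusted p = 0.0631) and with the dimmest 40% of genes left out (0.0754). The BMP and TGF-beta list had 4 of 27 higher and 9 lower, or 4 and 10 adjusted over the list alone (camera adjusted p = 0.0258; adjusted p = 0.585 with an estimated correlation). The ligand gene Bmp4 rose 10.9-fold, and Grem1, a BMP antagonist, and Ltbp2 were 12.9-fold and 10.3-fold lower, Ltbp2 being at background in HF-TAC. The Bmp4 log2 difference was 4.09 without HF-TAC replicate 1 and 2.80 without replicate 2. This list missed the threshold without HF-TAC replicate 1 (adjusted p = 0.22) and with the dimmest genes left out (0.0566).

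Of the 11 lists of markers of other cells, 2 passed as higher in HF-TAC beside the hair lineage genes. Whether matrix cells carried these transcripts or other cells entered the HF-TAC sort was not tested. Of the infundibulum, isthmus and sebaceous gland list 8 of 13 rose, or 9 adjusted over the list alone (median log2 difference 1.63, camera adjusted p = 1.45e-05; adjusted p = 0.398 with an estimated correlation). Krt79, a keratin of the upper follicle, rose 27.8-fold from 320 ± 111 to 8919 ± 3217 (SD, n = 2), Defb6 20.7-fold and Gata6 13.7-fold. Of the differentiated keratinocyte list 8 of 14 rose and 1 fell, or 9 and 1 adjusted over the list alone (median log2 difference 1.79, camera adjusted p = 7.78e-06; adjusted p = 0.398 with an estimated correlation), with Dsc1 10.9-fold and Ivl, involucrin, 8.66-fold higher. Dcn, of the fibroblast list, rose 68.4-fold (6.10 ± 0.36 SE, adjusted p = 0.000207), through 1 of its 2 probe sets. Other genes of that list fell, Sparc being 32.0-fold and Col5a1 6.24-fold lower, and the list of 12 did not pass (adjusted p = 0.156), except without HF-TAC replicate 2 (adjusted p = 0.0147). Of the melanocyte list Kit rose 9.79-fold and Mitf was 2.04-fold lower, and the list of 13 did not pass (adjusted p = 0.29). With the mean of each gene's probe sets the log2 differences were 3.16 for Dcn, -3.37 for Sparc, -1.45 for Col5a1, 1.97 for Gata6, 2.26 for Dsc1 and 1.83 for Kit, all past the threshold. Without HF-TAC replicate 1 they were 3.15 for Gata6, 2.77 for Dsc1 and 3.96 for Kit, and without HF-TAC replicate 2 they were 4.39, 4.14 and 2.63. The Defb6 difference was 5.10 and 3.65 without aHF-SC replicates 1 and 2, and Kit was at background in aHF-SC. The stress list was lower in HF-TAC, with 3 of 20 falling, also 3 adjusted over the list alone (camera adjusted p = 0.0074; adjusted p = 0.647 with an estimated correlation), and missed the threshold without aHF-SC replicate 2 (adjusted p = 0.093) and without HF-TAC replicate 2 (0.185).

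Other large rises were in Tnfrsf19, a TNF receptor family gene (35.2-fold), Aldh1a1, of retinoic acid synthesis (31.7-fold), and Aadac (30.4-fold). Other large falls were in Col6a1 (95.6-fold), Gdf10 (77.2-fold), Krt24 (71.7-fold), Gfra2 (57.4-fold) and S100a4 (35.0-fold). With the mean of each gene's probe sets the log2 differences were 2.97 for Tnfrsf19 and -2.0 for Gfra2. Without HF-TAC replicates 1 and 2 they were 4.06 and 5.80 for Aadac, and -5.60 and -6.94 for Gdf10. Aldh1a1 was at background in aHF-SC, and Col6a1 and Gfra2 were in HF-TAC. The Gfra2 value was -0.28 on the log2 scale and did not pass without the cross-hybridising probe sets (adjusted p = 0.395). In all, 1632 genes were higher and 1559 lower in HF-TAC than in aHF-SC by limma, and 174 and 249 by the test against a 2-fold change. The arrays did not overlap for 54.3% of genes, against 33.3% by chance. The counts were 963 and 1280 without aHF-SC replicate 1, 766 and 877 without aHF-SC replicate 2, and 1075 and 1177 without HF-TAC replicate 2. Of the 101 named genes past the threshold, 93 passed without aHF-SC replicate 1, 83 without aHF-SC replicate 2, 96 without HF-TAC replicate 1 and 91 without HF-TAC replicate 2, and 81 passed whichever array was left out. Dnmt1 and Mki67 were not among these 81.

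**Figure D2:**
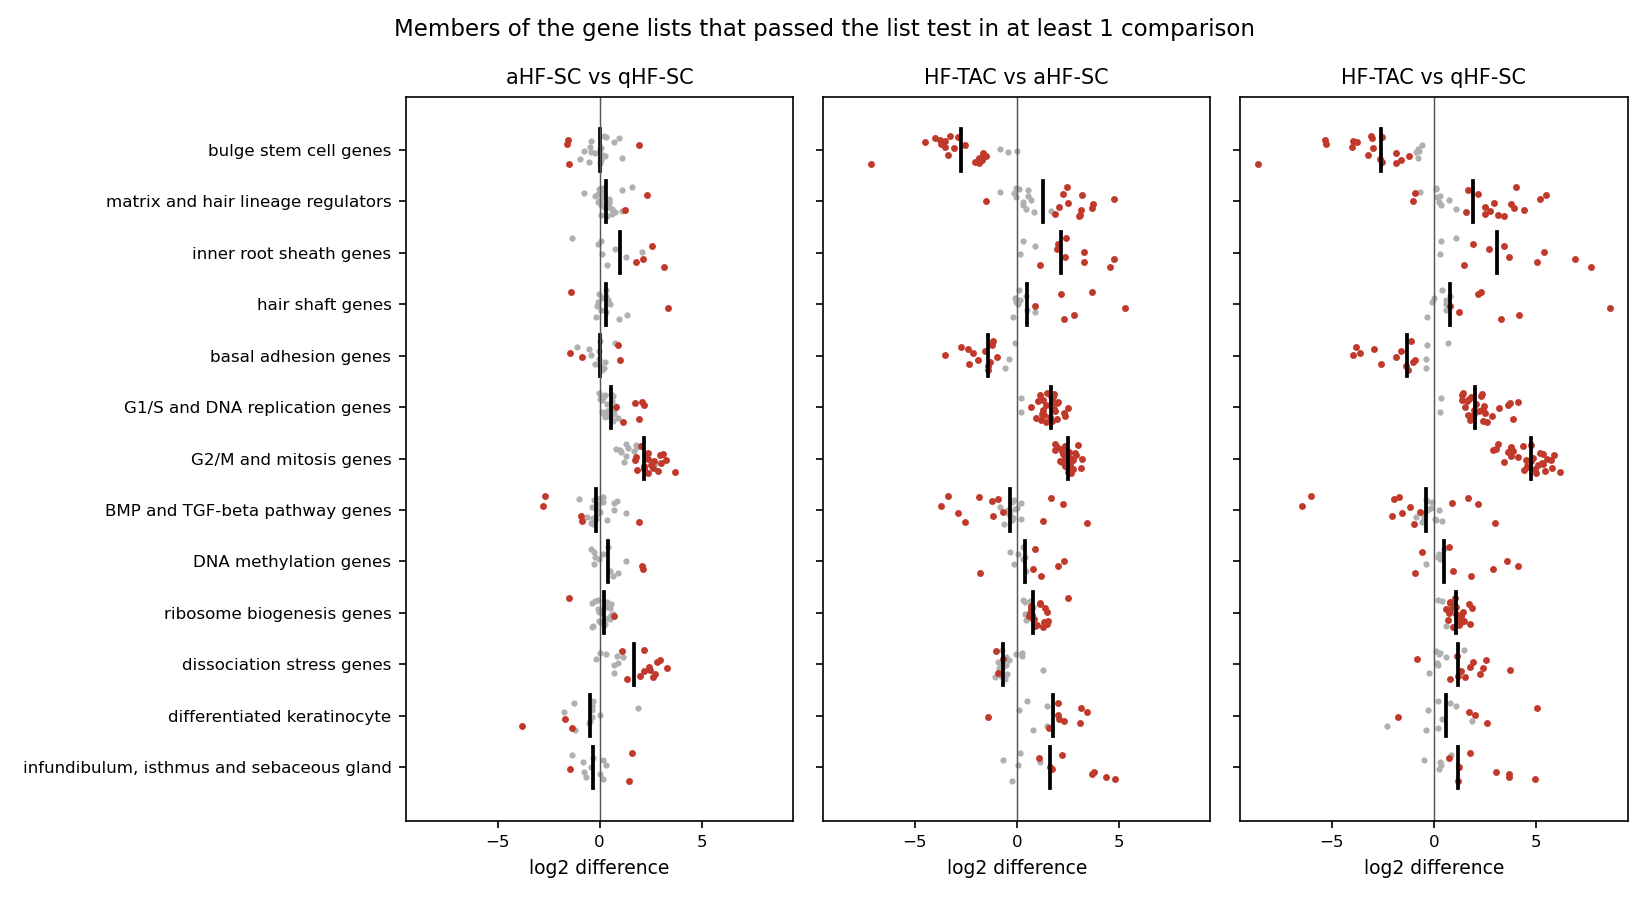
Log2 difference (x axis) of the members of the 13 lists that passed the camera test in at least 1 comparison; each dot is a gene, red where its own adjusted p was under 0.05, and the black bar is the list's median. Bulge genes centre on 0.0177 between the stem cell groups and on -2.71 in HF-TAC against aHF-SC, while mitosis genes lie above 0 in all 3 panels.

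HF-TAC against qHF-SC spans the whole lineage, with age, sorting scheme and cell type all differing. The largest rises by fitted fold were in Krt35, a hair keratin gene, 395-fold (8.62 ± 0.47 SE, adjusted p = 6.27e-05), from 14.1 ± 2.97 to 6032 ± 3540 (SD, n = 2), in Dcn of the fibroblast list, 213-fold, in the inner root sheath keratin genes Krt25, 209-fold, and Krt28, 122-fold, and in Ccnb2, 73.7-fold, Krtap8-1, 72.8-fold, the cytokinesis gene Cep55, 62.2-fold, and the claudin gene Cldn10, 60.9-fold. Dcn and Cep55 each rested on 1 of 2 probe sets, and with the mean of them their log2 differences were 3.90 and 3.29. The Krt35 difference was 9.26 and 7.99 without HF-TAC replicates 1 and 2. Krt35, Krt25, Krt28, Ccnb2, Krtap8-1 and Cep55 were at background in qHF-SC, and Col6a1, Col8a2 and Cck, among the falls, in HF-TAC. Apart from Cd34, the largest falls by fitted fold were in Krt24, a keratin gene (294-fold; -8.20 ± 0.25 SE, adjusted p = 1.51e-05), Col6a1 (221-fold), Col8a2 (148-fold), S100a4 (118-fold), Angptl7 (108-fold), Cck (97.2-fold) and Ccn2, a YAP target gene (92.1-fold).

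The 31 G2/M genes all rose, also adjusted over the list alone (median log2 difference 4.78, camera adjusted p = 4.02e-26; adjusted p = 0.396 with an estimated correlation). Of 30 G1/S genes 28 rose, likewise adjusted over the list alone (camera adjusted p = 9.31e-20; adjusted p = 0.396 with an estimated correlation), and of 25 ribosome biogenesis genes 22, or 23 adjusted over the list alone (camera adjusted p = 5.88e-11; adjusted p = 0.396 with an estimated correlation). Mki67 rose 40.3-fold (log2 difference 6.12 and 4.54 without qHF-SC replicates 1 and 2) and Uhrf1 17.3-fold. Of 22 bulge genes 17 fell, or 22 adjusted over the list alone (median log2 difference -2.6, camera adjusted p = 7.12e-16; adjusted p = 0.396 with an estimated correlation); Postn and Dkk3 were 39.9-fold and 39.0-fold lower, and Tcf7l1 (-0.76 ± 0.27 SE, adjusted p = 0.0809) did not pass, but did with the mean of its probe sets (0.039), with scaling to the 75th percentile (0.0399) and without either aHF-SC array (0.0226). Of 16 adhesion genes 12 fell, or 12 with 1 higher adjusted over the list alone (camera adjusted p = 3.99e-08; adjusted p = 0.396 with an estimated correlation).

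Of the matrix regulators 15 of 26 rose and 2 fell, or 17 and 3 adjusted over the list alone (median log2 difference 1.92, camera adjusted p = 1.58e-07; adjusted p = 0.396 with an estimated correlation), with Wnt5a 44.8-fold, Shh 37.3-fold and Dlx4 21.3-fold higher. With the mean of each gene's probe sets the log2 differences were 3.14 for Wnt5a, 2.84 for Shh and 3.56 for Dlx4, and Wnt5a was at background in qHF-SC. Hoxc13 (1.09 ± 0.34 SE, adjusted p = 0.0559) did not pass, but did under 6 other settings (adjusted p from 0.0197 to 0.0485) and without HF-TAC replicate 1 (1.64, adjusted p = 0.00424). Inner root sheath genes (9 of 12 higher, 9 adjusted over the list alone, camera adjusted p = 3.74e-08; adjusted p = 0.396 with an estimated correlation) and hair shaft genes (7 of 15, or 9 adjusted over the list alone, camera adjusted p = 0.000164; adjusted p = 0.396 with an estimated correlation) rose too. Of 13 DNA methylation genes 6 rose and 2 fell, or 7 and 3 adjusted over the list alone (camera adjusted p = 0.00953; adjusted p = 0.396 with an estimated correlation); without the cross-hybridising probe sets the list missed the threshold (adjusted p = 0.0908). Ezh2 rose 4.20-fold. In the BMP and TGF-beta list 4 of 27 rose and 9 fell, or 4 and 10 adjusted over the list alone (camera adjusted p = 0.0385; adjusted p = 0.666 with an estimated correlation), Grem1 being 87.6-fold lower and Bmp4 7.99-fold higher (log2 difference 3.64 and 2.35 without HF-TAC replicates 1 and 2). That call ended without qHF-SC replicate 1 (adjusted p = 0.0642), without HF-TAC replicate 1 (0.209), with the mean of each gene's probe sets (0.251) and with the dimmest genes left out (0.1).

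Infundibulum, isthmus and sebaceous gland markers were higher in HF-TAC here too, 8 of 13 rising, also 8 adjusted over the list alone (camera adjusted p = 0.000152; adjusted p = 0.396 with an estimated correlation), with Krt79 30.7-fold higher. Stress genes were higher in HF-TAC than in qHF-SC, 11 of 20 rising and 1 falling, or 12 and 1 adjusted over the list alone (median log2 difference 1.17, camera adjusted p = 0.000164; adjusted p = 0.609 with an estimated correlation), with Egr2 13.3-fold (log2 difference 4.43 and 3.05 without qHF-SC replicates 1 and 2) and Nr4a1 5.88-fold higher. Of the differentiated keratinocyte list 4 of 14 rose and 1 fell, or 5 and 2 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.117) except without qHF-SC replicate 1 (adjusted p = 0.0327), without HF-TAC replicate 2 (0.00431) and with the replicate number as a block (0.0454). Sprr1a of that list rose 32.6-fold, with a log2 difference of 6.14 without qHF-SC replicate 1 and 3.92 without qHF-SC replicate 2. Of the melanocyte list Mitf was 19.7-fold lower and Kit and Dct were 10.8-fold and 3.69-fold higher; the list of 13 did not pass (adjusted p = 0.152), except without HF-TAC replicate 1 (adjusted p = 0.0474). With the mean of each gene's probe sets the log2 differences were -2.89 for Mitf and 1.86 for Kit. Kit was at background in qHF-SC, and its difference was 4.10 and 2.77 without HF-TAC replicates 1 and 2.

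By limma, 2445 genes were higher and 2345 lower in HF-TAC than in qHF-SC, and 440 and 490 by the test against a 2-fold change. The arrays did not overlap for 61.2% of genes, against 33.3% by chance. Of the called genes, 62 had another probe set past the threshold in the opposite direction, none of them among the genes named. The counts were 1635 and 1557 without qHF-SC replicate 1 and 1361 and 1532 without qHF-SC replicate 2. Of the 112 named genes past the threshold, 102 passed without qHF-SC replicate 1, 98 without qHF-SC replicate 2, 110 without HF-TAC replicate 1 and 102 without HF-TAC replicate 2, and 96 passed whichever array was left out.

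None of the list calls held with an estimated correlation: 0 lists passed in each comparison, and 0, 3 and 3 had an unadjusted p under 0.05, while by fry 0, 13 and 12 lists passed, of which 0, 11 and 11 were among those past camera. By fry the BMP and TGF-beta list (adjusted p = 0.0622) and the stress list (0.245) did not pass in HF-TAC against aHF-SC, nor the stress list in HF-TAC against qHF-SC (0.0975). A further 17 lists did not pass camera at the preset correlation in any comparison. Their lowest adjusted p was 0.332 for CDK inhibitors, 0.757 for the Wnt list, 0.147 for the Hedgehog list, 0.634 for the Notch list, 0.488 for Polycomb genes, 0.295 for histone demethylases and trithorax genes, 0.239 for glycolysis and 0.599 for non-skin transcription factors. Among the markers of other cells it was 0.771 for the companion layer, 0.156 for fibroblasts, 0.152 for the dermal papilla, 0.152 for melanocytes, 0.578 for endothelial, 0.1 for immune, 0.382 for Merkel and Schwann, 0.0881 for muscle and 0.853 for erythroid cells. By fry the dermal papilla list passed as higher in HF-TAC than in aHF-SC (adjusted p = 0.0109) and than in qHF-SC (0.00578), and the muscle list as lower in HF-TAC than in aHF-SC (0.0327). The Hedgehog list passed without HF-TAC replicate 2, as lower in HF-TAC than in aHF-SC (adjusted p = 0.0149) and than in qHF-SC (0.0303). The fibroblast list passed as lower than in qHF-SC without that same array (adjusted p = 0.0474), the glycolysis list as lower in HF-TAC than in aHF-SC without HF-TAC replicate 1 (0.027), and the immune list as lower in aHF-SC than in qHF-SC without qHF-SC replicate 1 (0.0281). Between HF-TAC and qHF-SC, 8 of 32 Wnt genes fell and 6 rose, or 10 and 8 adjusted over the list alone, with Lef1 15.3-fold higher and Sfrp1 13.8-fold lower (log2 difference -3.14 with the mean of its probe sets), and the median of 0.137 and the mean of -0.104 on the log2 scale differed in sign. Median, mean and test also differed in sign for the Wnt and companion layer lists in the other comparisons, for the companion layer here, for the Hedgehog, Polycomb and dermal papilla lists in aHF-SC against qHF-SC, and for the endothelial list in both comparisons with aHF-SC. Of 11 Hedgehog genes 2 rose and 4 fell there, also 2 and 4 adjusted over the list alone; Shh rose and its co-receptor genes Cdon (12.2-fold), Gas1 (7.26-fold) and Boc (4.57-fold) were lower, with log2 differences of -1.94 for Cdon and -2.19 for Gas1 with the mean of their probe sets. Of 14 Notch genes 3 rose and 3 fell, or 3 and 4 adjusted over the list alone. Of 26 non-skin transcription factor genes 1 rose, Olig1 (1.99-fold, from background), and 1 fell, Lmx1b (2.02-fold lower), in the same comparison. The Lmx1b call ended without qHF-SC replicate 1 (adjusted p = 0.0844) or 2 (0.0735) and without HF-TAC replicate 2 (0.0691).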

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

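The crossed pairing and the counts without cell cycle and stress genes were chosen after the results were seen; the other settings were planned. Genes higher and lower in aHF-SC than in qHF-SC numbered 17 and 41 by the test against a 2-fold change, and 417 and 383 with at least a 2-fold difference. For HF-TAC against aHF-SC the same settings gave 174 and 249, then 914 and 1010; for HF-TAC against qHF-SC 440 and 490, then 1392 and 1426. These settings ask for more than the main test by construction. With 1 array left out, the counts ranged from 54 to 634 higher and 70 to 720 lower in aHF-SC against qHF-SC, from 766 to 1550 and 877 to 1316 in HF-TAC against aHF-SC, and from 1361 to 2308 and 1532 to 2280 in HF-TAC against qHF-SC; fewer arrays enter each such fit. Under the other probe set, filter, scaling, prior and weighting settings the counts stayed within 1.5 times the main ones. The genes behind the counts changed more. With the mean of each gene's probe sets, 417 of the 558 higher and 407 of the 584 lower genes in aHF-SC were shared. Estimated weights were equal for the 2 arrays of each group, so they could not set a replicate apart. The scalings moved the median over genes by at most 0.0314 on the log2 scale.

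The numbers of lists past the threshold were 6, 13 and 12 for the 3 comparisons, and from 6 to 8, 12 to 14 and 12 to 15 with 1 array left out. By camera with an estimated correlation they were 0, 0 and 0, with 0, 3 and 3 lists at an unadjusted p under 0.05. That setting widens the error of lists whose members vary together, but it also rests on 3 residual degrees of freedom. The muscle list in aHF-SC against qHF-SC had an estimated correlation of -0.0236. Its unadjusted camera p still went from 0.0235 to 0.0999. By fry the numbers were 0, 13 and 12, with 5, 14 and 15 at an unadjusted p under 0.05. Acta2 reversed in all 3 comparisons without the _x_at and _s_at probe sets, to -0.1545, 0.1513 and -0.003182 on the log2 scale, where another probe set takes its place; the cause of the difference between its probe sets was not tested. Over all settings, 6198 values of named genes kept their side of the threshold, 438 lost it, 70 gained it and 3 reversed. For lists these numbers were 1545, 54, 18 and 0. Direction was compared only where a value passed in the main fit or under the setting. Lgr5 in aHF-SC against qHF-SC counts as kept, though it went from 0.06 to -0.24 with the mean of its probe sets. The setting without cell cycle and stress genes repeats the main fit, so its values were kept by construction. With no detection calls, signal over background limits what can be said of dim genes.

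Replicate numbers are shared between the groups. Deviations of same-numbered arrays correlated at 0.0615 between qHF-SC and aHF-SC, 0.0838 between aHF-SC and HF-TAC and -0.127 between qHF-SC and HF-TAC, so the numbers were not taken as pairs. With the number as a block the counts were 410 and 479, 1422 and 1414, and 2304 and 2226. With crossed numbers as the block, HF-TAC against qHF-SC gave 2412 and 2343. Without the cell cycle and stress lists the counts were 520 and 584, 1573 and 1556, and 2375 and 2344.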

Other observations

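The tests of carry-over between sorts and of handling were chosen after the results they bear on were seen; the test of clock phase was chosen after Dbp and Nr1d2 were seen, on other clock genes not yet examined, and those of RNA quality and age were written before. Among the 2445 genes higher in HF-TAC than in qHF-SC, aHF-SC lay at a median of 32.2% of the log2 distance from qHF-SC to HF-TAC, and among the 2345 lower genes at 37.5%. The gene groups differed in this position. The 17 bulge genes called between the ends stood at a median of 0.058%, the 12 adhesion genes at 6.3%, the 22 ribosome biogenesis genes at 22.4%, the 28 G1/S genes at 25.8%, the 9 inner root sheath genes at 34.9% and the 31 mitosis genes at 45.5%. These are descriptions of the group means, with no test between the groups.

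Clock genes were a group outside the fixed lists, singled out after Dbp appeared among the largest falls and Nr1d2 was seen. Against qHF-SC, the aHF-SC levels on the log2 scale were -3.70 ± 0.224 (SE) for Per2, -3.68 ± 0.207 for Tef, -3.47 ± 0.249 for Per3, -2.45 ± 0.191 for Hlf and -1.84 ± 0.311 for Per1, all past the threshold by limma. Arntl, of the opposite phase, was higher by 1.91 ± 0.216. In HF-TAC the same 5 genes were lower than in qHF-SC, and between HF-TAC and aHF-SC 0 of the 8 genes that peak with Dbp passed by limma, with 1 at an unadjusted p under 0.05. Of the 5 genes of the opposite phase 3 were lower in HF-TAC than in aHF-SC, Npas2 (-2.60), Nfil3 (-1.89) and Clock (-0.719), and 4 were lower than in qHF-SC.

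A shift in clock phase, as another hour of tissue collection would give, may account for this pattern. The median difference of 8 genes that peak with Dbp minus that of 5 genes of the opposite phase was -2.68 in aHF-SC against qHF-SC (exact permutation test over genes, two-sided p = 0.035; genes are not independent replicates). Of the opposite phase only Arntl passed as higher there, and Cry1 went against it with a log2 difference of -1.21. The same value for HF-TAC against qHF-SC was -1.44 (exact p = 0.172), where 4 of 5 genes of the opposite phase fell, against a shift in phase, and Arntl was higher by 1.23, as a shift would give. An effect of stem cell activation cannot be told apart from the hour of collection, since 0 arrays carry that hour in their labels, and an effect of age stays open as untested.

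Division genes higher in aHF-SC than in qHF-SC could come from HF-TAC carried over into the aHF-SC sort, which would bring hair lineage transcripts in the same share as mitosis transcripts; that sort used CD34, whose transcript was at 20.5 in HF-TAC. On the linear scale aHF-SC reached a median of 15.4% of the HF-TAC level above qHF-SC for 31 mitosis genes and 6.41% for 25 hair lineage genes, a difference of -8.98 percentage points (permutation test over genes, two-sided p = 1e-05, the smallest that the resamples can give; genes that vary together are taken as independent). The difference rested on 1 array: aHF-SC replicate 1 had 22.3% and 2.08%, a difference of -20.3, and replicate 2 had 7.73% and 6.73%, a difference of -0.997 (permutation p = 0.432). Carry-over therefore cannot be told apart from division of the stem cells themselves. The same holds for the hair lineage genes higher in aHF-SC, which could be carried over or made by the stem cells. Of the inner root sheath genes that rose there, the shares were 3.94% for Krt25, 7.53% for Krt27, 2.77% for Krt28 and 47.5% for Padi3. Age and sorting scheme cannot be told apart from stem cell state either, as 0 other populations of either stem cell group differ in age or sort.

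Stress genes were higher in aHF-SC than in qHF-SC. The log2 ratio of 3' to 5' control probe sets, a sign of RNA quality, differed between these groups by -0.192 for beta-actin and -0.152 for Gapdh, the genes named for the test, and by -0.44 for pyruvate carboxylase and 0.31 for the dim transferrin receptor, which argues against a large difference in RNA degradation or labelling. Handling of the younger skins before lysis cannot be told apart from their age or growth, which were not tested. The list was also higher in HF-TAC than in qHF-SC (median log2 difference 1.17), but both comparisons share the 2 qHF-SC arrays. Both calls were lost in the 2 other list tests. By camera with an estimated correlation the adjusted p was 0.749 for aHF-SC and 0.609 for HF-TAC against qHF-SC. By fry it was 0.171 and 0.0975 in the same order.

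Probe sets without a single gene symbol were tested in the same way but not named. Of 10092, 99 were higher and 203 lower in aHF-SC than in qHF-SC, 216 and 208 in HF-TAC against aHF-SC, and 363 and 617 in HF-TAC against qHF-SC.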
